A study of Mus musculus with 6 samples.

How the data were processed

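RNA was measured in 6 mouse samples at embryonic day 9.5. Per the labels, cells were freshly isolated from 3 tissues (heart tube, caudal-half tissue of the embryo and yolk sac) of mixed-background mice and sorted by flow cytometry for CD31 on the surface and against CD41 and CD45. CD31 marks endothelial cells, CD41 megakaryocytes and early blood progenitors, and CD45 leukocytes, so the labels call the fractions enriched for endothelium. Each tissue was sampled as 2 independent biological replicates, each hybridised to its own Affymetrix mouse array after biotin labelling. Per the labels' protocols RNA was extracted with a column kit and labelled by the manufacturer's standard method. The number of embryos behind a sample is not given in the sources used here.

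The deposited signal of each probe set was made by the authors with RMA in the affy package, per the submitters' processing notes. RMA corrects background, forces all arrays to share the same distribution of probe values and summarises the probes of a set. Versions, filters and the chip definition are not given in the sources used here. The deposited signals ran from 2.46 to 2172540. A 16-bit scanner cannot exceed 65535, and RMA values on the log2 scale rarely pass the corresponding limit of 16, while log2 of the highest deposited signal would be 21.1. The natural log of the deposited signals ran from 0.899 to 14.6, the usual range of RMA log2 values. The natural log of each deposited signal was therefore read as the authors' RMA log2 value, as if the base had been exchanged on back-transformation.

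That reading is a limit on every size of difference reported here, since the base is not stated. If the deposited signals are linear after all, each log2 difference and its standard error must be multiplied by 1.44, while limma p-values against no difference and the counts of genes called by them do not change. Counts with a minimum difference do change. The hybridisation controls, at nominal concentrations of 1.5, 5, 25 and 100 pM, rose by 0.707 to 0.804 per doubling on the scale used here and by 1.02 to 1.16 on the other, and did not decide between the scales. The design fixed before the data were examined had assumed log2 values, and the test was kept after this conversion.

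The value table held 45101 probe sets, of which 64 were manufacturer's controls. In the platform annotation 34958 probe sets carried 1 gene symbol (13 of them controls), 932 several and 9211 none. Of the named probe sets, 34754 matched by Entrez identifier in a gene table of the GRCm38.p6 assembly, which gave 0 newer symbols. No genome build is named for the values, so coordinates are not given. A gene was represented by the probe set of its own with the highest mean over all 6 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. Genes fixed in lists but without such a probe set (Hbb-b1, Ahsp, Gp1ba, Trf, T, Hoxd4, Hoxa6, Hoxb8, Ccnb1, Gapdh, Eno1, Ddx3y and others that are not reported here) were not analysed here. The 27 probe sets for bacterial RNAs read 1.33 to 4.03 on the 6 arrays. Whether these RNAs were added to the samples is not stated, and the range serves only to describe weak signals.

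Tissue means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 6 arrays without a covariate, which left 3 residual degrees of freedom and gave 3.48 prior degrees of freedom at a prior standard deviation of 0.210. The 3 pairwise differences were tested two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The number of arrays limits the precision: the median standard error of a difference was 0.210, and the smallest called differences were 0.64 to 0.73. Genes called in the same direction against both other tissues were counted for each tissue. Because these 2 comparisons share arrays, the overlap was also computed in 100 simulations of groups without any difference, with lists of the observed sizes, and as the overlap of independent lists. With 2 arrays per tissue, regroupings of the arrays were not counted.

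The 23 gene lists were fixed before the data were examined, and the 21 with at least 5 measured genes were tested in each comparison with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 63 tests. Of the 33 tests that passed, 12 also passed with an estimated correlation and 33 with limma's fry, which asks only whether a list's genes move one way. For some lists the estimated correlation was below the preset 0.01, as for epithelial genes (-0.0615), and p rose there too. A call lost in that setting therefore does not by itself show that the genes of a list vary together. Fry also passed tests that camera did not, so its passes add little. 5 genes belonged to more than 1 list. Genes named in the text were also set by a rule before the data were examined. In each comparison it takes up to 6 genes per direction with the largest difference, up to 4 called members per list, 15 genes named whatever their test, and 5 genes per tissue and direction that stood apart from both other tissues. Genes without an official symbol were counted but not named, and about 30 genes per comparison were kept in the text. Other genes are said to be outside the rule.

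The steps were tested on simulated data with the mean level of each of 18193 genes and 200 genes changed in the heart tube. The noise had the spread that limma fitted to each gene, moved toward a common value, and not the raw spread. Recovery and false calls may therefore look better than in the real data. In the simulated comparison of heart tube with caudal-half tissue, 98% of genes changed by 2 log2 units were recovered, 22% of those changed by 1 and 2% of those changed by 0.5. In that comparison 5 of the 116 calls were false. Of 100 random lists of 20 unchanged genes, 1 passed an unadjusted p of 0.05, and the list of raised genes passed. The noise was drawn for each gene on its own. The check therefore does not cover lists whose genes vary together, such as the pan-endothelial list (estimated correlation 0.145).

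Alternatives fixed before the data were examined were the replicate number as a block, the mean of all probe sets of a gene, removal of probe sets that share sequence, removal of dim genes, cyclic loess, centring of arrays on their medians, robust and trended variances, a minimum difference of 0.5 (limma treat), all probe sets, only the 4 arrays of the tissues compared, and leaving out each array. A minimum difference on the literal log2 scale and removal of genes within the range of the bacterial controls were added after seeing the data. Values were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plotted with matplotlib 3.10.9.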

Results

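Expression was profiled in endothelium-enriched cells of the mouse embryo at day 9.5, sorted as CD31-positive, CD41-negative and CD45-negative from the heart tube, the caudal-half tissue and the yolk sac. There were 6 arrays, 2 independent biological replicates per tissue. Levels are RMA values of the authors, read as log2 from the natural log of the deposited signals. If the deposited signals are linear, every difference is larger by a factor of 1.44, and limma's tests against no difference do not change. Over all probe sets without controls, replicate arrays correlated at r = 0.981 to 0.986 and arrays of different tissues at 0.947 to 0.969. The SD of the difference between replicates was 0.430 to 0.493, and that between tissues 0.635 to 0.823. The 3' minus 5' signal of the Gapdh controls, a measure of RNA integrity and labelling, was 1.67 and 1.58 in the caudal-half tissue, 1.88 and 1.98 in the heart tube, and 2.04 and 1.81 in the yolk sac. The corresponding difference for beta-actin lay between -0.10 and 0.01 on all 6 arrays.

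The genes of the sort and of endothelium in general were measured first. Pecam1, which encodes CD31, was at 9.55 ± 0.08 (SD, n = 2) in the heart tube, 9.95 ± 0.18 in the caudal-half tissue and 9.96 ± 0.19 in the yolk sac, and passed no test. Ptprc, which encodes CD45, read 2.47 to 2.79 in the 3 tissues, within the range of the bacterial controls (1.33 to 4.03). Itga2b, which encodes CD41, was higher in the yolk sac (8.28 ± 0.13, n = 2) than in the heart tube (6.87 ± 0.09) and caudal-half tissue (6.61 ± 0.27), with limma adjusted p of 0.00687 and 0.00522. Of the 3 genes of the sort, none passed in the comparison of heart tube with caudal-half tissue, where 3556 genes had an unadjusted p under 0.05. None of the 24 pan-endothelial genes was within the range of the bacterial controls in any tissue, and their median level was 9.33 in the heart tube, 9.93 in the caudal-half tissue and 9.98 in the yolk sac.

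**Figure D1:**
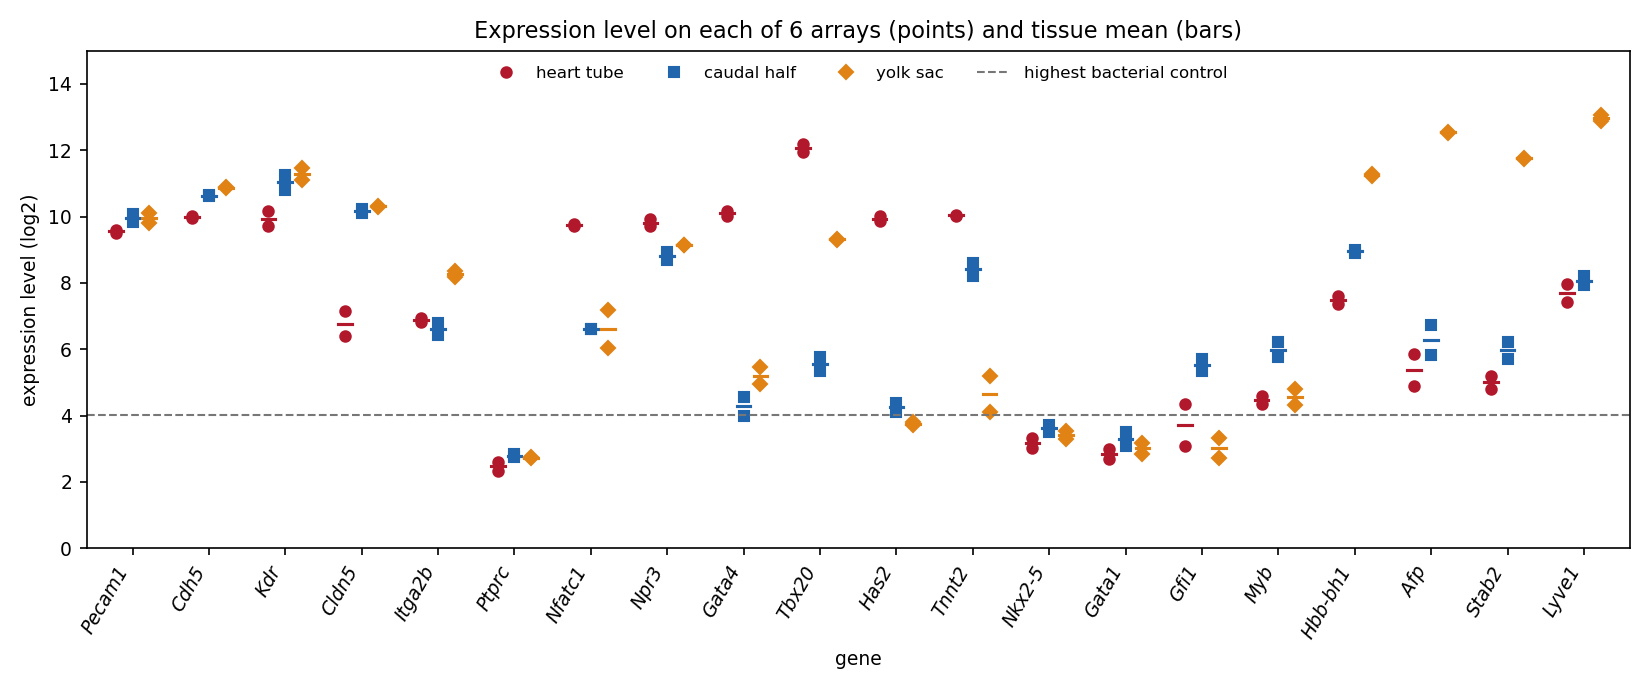
Expression level (log2) of 20 genes on each array, with points for the 2 replicates of each tissue, short bars for tissue means and a dashed line at the highest bacterial control. The Pecam1 means lie between 9.55 and 9.96, whereas the Nfatc1 mean is 9.76 in the heart tube and 6.62 and 6.61 in the caudal-half tissue and yolk sac.

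The comparison of heart tube with caudal-half tissue asks what sets the lining of the early heart apart from endothelium of the trunk, which includes the embryo's own blood-forming region. The transcription factor gene Tbx20 was far higher in the heart tube, where it reached 12.06 ± 0.16 against 5.56 ± 0.30 (n = 2 each), a difference of 6.51 ± 0.20 (SE). Gata4 differed by 5.82, Gata5 by 5.31 and Hand2 by 4.25. Nfatc1, a transcription factor of the endocardium needed for valve formation, was higher by 3.14 ± 0.35. Npr3, a natriuretic peptide receptor of the endocardium, was higher by 1.00 ± 0.18. Of the 18 endocardial genes, 11 were higher and 0 lower (14 and 1 adjusted over the list alone), with a median difference of 1.87 and an adjusted p of 2.42e-14 in limma's camera (0.047 with an estimated correlation). The genes of cushion formation and mesenchymal transition moved likewise, with 8 of 18 higher and 0 lower (12 and 3 adjusted over the list alone). They included Has2, the hyaluronan synthase of cardiac jelly (5.69 ± 0.18), Vcan, the proteoglycan versican (4.83), Sox9 (4.36) and Twist1 (3.48). The adjusted p for this list was 3.91e-10 (0.047 with an estimated correlation).

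Markers of other cell types also differed in this comparison. Of the 24 cardiomyocyte genes, 8 were higher in the heart tube and 0 lower (17 and 0 adjusted over the list alone; camera adjusted p = 2.02e-11, and 0.047 with an estimated correlation). Tnni1, a slow troponin, was higher by 3.97 ± 0.25 and Myl7, the atrial myosin light chain, by 3.69 ± 0.30. Tnnt2, cardiac troponin T, was at 10.04 ± 0.02 in the heart tube and 8.41 ± 0.29 in the caudal-half tissue, a difference of 1.63 that missed the threshold (limma adjusted p = 0.0523). Of its 3 probe sets, 1 passed (1.97, limma adjusted p = 0.0316 over all named probe sets). Its caudal arrays (2.86 and 3.39) were within the range of the bacterial controls. The cardiac transcription factor Nkx2-5 read 3.17 to 3.62 in the 3 tissues, within the range of the bacterial controls, and passed no test. Of 16 mesenchymal genes, 6 were higher and 1 lower (7 and 4 adjusted over the list alone), led by Tcf21 (4.08) and the collagen gene Col3a1 (3.53), whereas the gut mesenchyme factor Foxf1, chosen after its values were seen, was lower (-2.04). For this list the median (-0.17) and the mean (0.81) differed in sign, and the adjusted p of 0.0305 in the direction of the mean rose to 0.183 with an estimated correlation. It also rose to 0.0881 without the first heart tube array, to 0.0554 without the second caudal array and to 0.206 without dim genes.

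Members of other lists were lower in the heart tube. Cldn5, the tight junction claudin of endothelium, was at 6.77 ± 0.53 in the heart tube and 10.16 ± 0.08 in the caudal-half tissue (n = 2 each), a difference of -3.40 ± 0.26. Of the 24 pan-endothelial genes, 7 were lower and 1 higher (14 and 3 adjusted over the list alone; camera adjusted p = 0.000294). That call was lost with an estimated correlation (adjusted p = 0.217). Among 22 arterial and Notch genes, 8 were lower, such as the gap junction gene Gja5 (-2.77) and the BMP receptor gene Acvrl1 (-2.47). Bmx (3.55) and Hey2 (2.30) were higher, and the counts adjusted over the list alone were the same. The adjusted p was 0.00169 (adjusted p = 0.175 with an estimated correlation). Of 12 venous and lymphatic genes, 3 were lower (Aplnr -2.21, Flt4 -1.47 and Nrp2 -1.46) and 0 higher (5 and 1 adjusted over the list alone), at an adjusted p of 0.0034 (0.145 as the adjusted p with an estimated correlation, and 0.0614 with the mean of all probe sets of a gene). Epithelial genes were lower in 6 of 14 (7 adjusted over the list alone), among them Epcam (-3.12) and the E-cadherin gene Cdh1 (-3.10), at an adjusted p of 3.07e-06 (adjusted p = 0.0573 with an estimated correlation).

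The Hox genes, which pattern the body axis, were lower in the heart tube without exception among those that passed. Of 13 measured members of paralogue groups 1 to 5, 8 were lower (11 adjusted over the list alone), with Hoxb5 at -3.88 ± 0.18. Of 19 members of groups 6 to 13, 12 were lower (13 adjusted over the list alone), with Hoxd8 at -5.60 ± 0.22, Hoxd9 at -5.07 and Hoxc10 at -4.63. Camera gave adjusted p of 2.66e-10 and 6.14e-14, each 0.047 with an estimated correlation. In the heart tube 12 of the 19 genes were within the range of the bacterial controls. Among 17 glycolysis and hypoxia genes, 3 were lower in the heart tube (10 adjusted over the list alone), namely Pdk1 (-1.60), Pfkp (-1.51) and the glucose transporter gene Slc2a1 (-1.36). Their adjusted p was 5.96e-07 (adjusted p = 0.0523 with an estimated correlation).

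**Figure D2:**
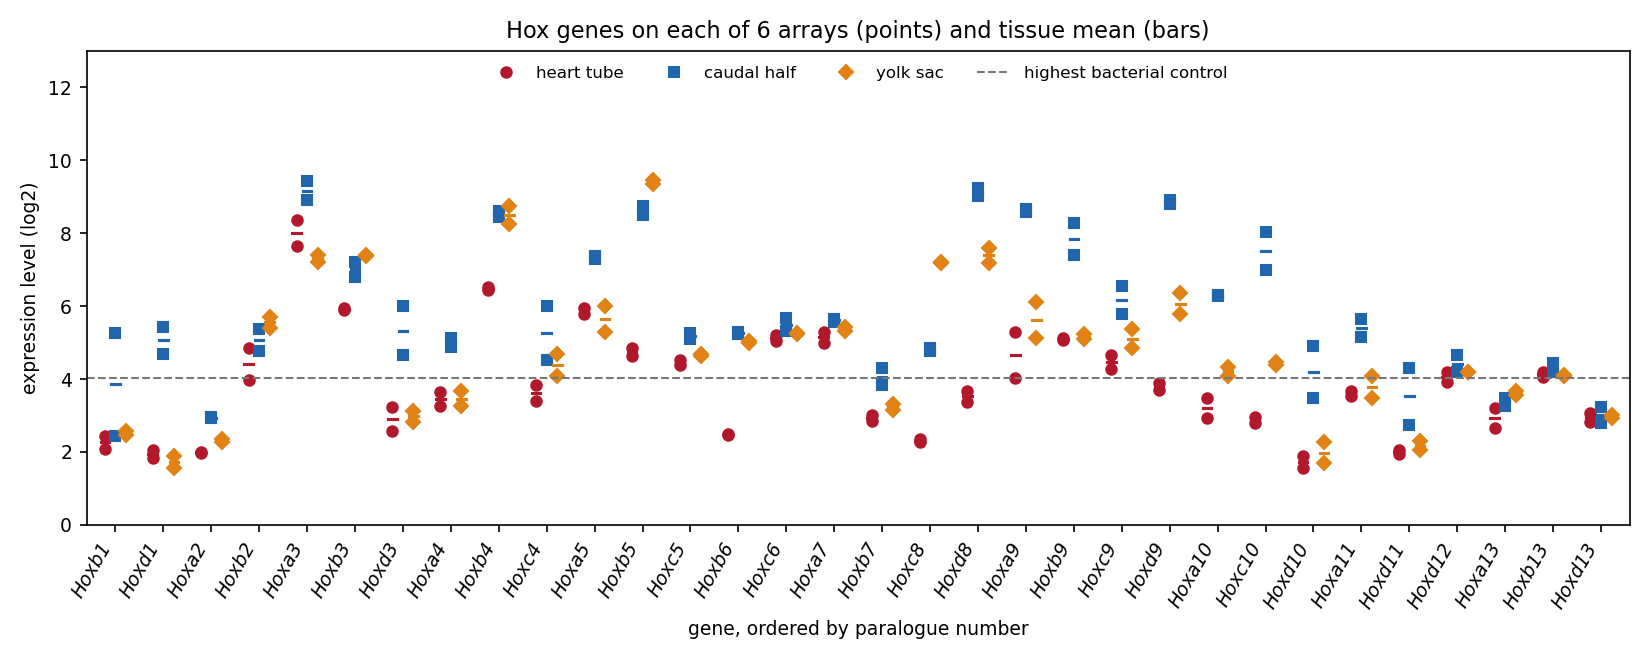
Expression level (log2) of the 32 measured Hox genes, ordered by paralogue number, with points for the 2 arrays of each tissue, short bars for means and a dashed line at the highest bacterial control. Hoxd9 averages 8.86 in the caudal-half tissue, 6.07 in the yolk sac and 3.79 in the heart tube.

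Over all 18193 genes, limma called 520 higher and 482 lower in the heart tube than in the caudal-half tissue (2.86% and 2.65%). The largest differences upward were Pdlim3, a PDZ and LIM domain protein of muscle (6.71), Tbx20 and Bmper, a regulator of BMP signalling (5.94). The largest downward were Dppa3, a gene of germ cells and the early embryo (-6.32 ± 0.17), Hoxd8, the pluripotency and neural factor Sox2 (-5.36) and the homeobox gene Rhox9 (-5.24). In 249 of the called genes the lower mean was within the range of the bacterial controls, as for Dppa3, Hoxd8, Hoxd9, Hoxc10, Sox2, Tcf21, Bmx, Cdh1 and Bmper, so that these differences depend on a signal near background. Without a single heart tube or caudal array the counts fell to between 208 and 285 higher and between 168 and 271 lower. Of the genes named here, Npr3 lost its call whichever of those 4 arrays was left out, Nrp2 and Slc2a1 without the first and the second heart tube array, and Pdk1 without the first heart tube or second caudal array (highest limma adjusted p 0.154).

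The comparison of heart tube with yolk sac sets the lining of the heart against the extraembryonic endothelium, where the first blood cells form. Among the largest differences were those of genes of the visceral endoderm, the epithelial layer that covers yolk sac vessels. Of 21 visceral endoderm genes, 17 were lower in the heart tube and 0 higher (18 and 0 adjusted over the list alone), with a median difference of -4.53 (camera adjusted p = 1.10e-18, and 0.047 with an estimated correlation). Transthyretin, encoded by Ttr, was at 12.42 ± 0.15 in the yolk sac and 4.85 ± 0.06 in the heart tube (n = 2 each), a difference of -7.57 ± 0.17. Rbp4, the retinol-binding protein, differed by -7.91 and Afp, alpha-fetoprotein, by -7.17 ± 0.40. Epithelial genes went the same way in 8 of 14 (9 adjusted over the list alone), with Cldn6 at -5.72 and Krt18 at -3.00, at an adjusted p of 8.39e-08 (0.0488 with an estimated correlation).

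Endothelial genes also separated these tissues. The hyaluronan and scavenger receptor genes Stab2 and Lyve1 were lower in the heart tube by -6.75 ± 0.24 and -5.26 ± 0.23. The mannose receptor gene Mrc1, of macrophages and some endothelium, differed by -5.50 and the fatty acid carrier gene Cd36 by -6.99. Of the 12 venous and lymphatic genes, 7 were lower (8 adjusted over the list alone) and Prox1, a lymphatic and cardiac transcription factor, was higher at 2.84 (2 higher adjusted over the list alone). The list's adjusted p was 6.05e-05, lost with an estimated correlation (adjusted p = 0.0865). Pan-endothelial genes were lower in 11 of 24 and higher in 0 (17 and 0 adjusted over the list alone), including Cldn5 (-3.54), Clec14a (-2.90) and Robo4 (-2.87), at an adjusted p of 2.39e-08 (adjusted p = 0.148 with an estimated correlation). Among the 22 arterial and Notch genes, 10 were lower and 4 higher (11 and 4 adjusted over the list alone), with Gja5 at -3.89, Acvrl1 at -3.71 and Bmx at 3.20. Their adjusted p of 0.0138 was lost with an estimated correlation (adjusted p = 0.217).

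Endocardial genes were higher in 12 of 18 and lower in 0 (13 and 0 adjusted over the list alone), led by Gata5 (5.57), Hand2 (4.92), Gata4 (4.90) and Nfatc1 (3.15 ± 0.35), at a camera adjusted p of 1.91e-11 (0.047 with an estimated correlation). Npr3 was not called against the yolk sac (0.68), and 0 of its 3 probe sets passed there. Cushion and transition genes were higher in 9 of 18 and lower in 1 (10 and 2 adjusted over the list alone), with Has2 at 6.18, Sox9 at 4.73 and Msx1 at 4.27. Their adjusted p of 6.82e-06 became 0.0652 as the adjusted p with an estimated correlation. Cardiomyocyte genes were higher in 10 of 24 and lower in 1 (16 and 1 adjusted over the list alone; adjusted p = 1.14e-09, and 0.047 with an estimated correlation). Tnnt2 was 5.38 ± 0.35 higher and Myl7 3.64. Erythroid genes were lower in 8 of 18 and higher in 0 (10 and 0 adjusted over the list alone), with the embryonic globin genes Hba-x at -3.91 and Hbb-bh1 at -3.76 ± 0.17. The camera adjusted p of 4.65e-06 became 0.0573 as the adjusted p with an estimated correlation. Of the Hox genes of groups 6 to 13, 6 of 19 were lower and 0 higher, the same adjusted over the list alone, with Hoxc8 at -4.88 (adjusted p = 0.000208, and adjusted p = 0.135 with an estimated correlation). The groups 1 to 5 missed the threshold (adjusted p = 0.0544), although Hoxb5 was at -4.65.

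Over all genes limma called 936 higher and 1214 lower in the heart tube than in the yolk sac (5.14% and 6.67%). Pdlim3 (7.55) and Foxc2, a forkhead factor (6.88), led upward. In 452 called genes the lower mean was within the range of the bacterial controls, as for Rbp4, Cd36, Cldn6, Pdlim3, Foxc2, Has2, Gata5, Hand2 and Hoxc8. Leaving out a single heart tube array lowered the counts to 387 or 413 higher and 549 or 611 lower, and leaving out the first yolk sac array to 560 and 746. Of the genes named here, Prox1 lost its call without either heart tube array or the second yolk sac array (highest limma adjusted p 0.098), and Itga2b without the first heart tube array (0.053).

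The comparison of caudal-half tissue with yolk sac sets an embryonic against an extraembryonic site of blood formation. Visceral endoderm genes were lower in the caudal-half tissue in 17 of 21 and higher in 0 (the same adjusted over the list alone), with a median difference of -4.31 and Ttr at -7.94 ± 0.17, Apob at -6.65 and Afp at -6.28 (camera adjusted p = 3.59e-21, and 0.047 with an estimated correlation). Erythroid genes were lower in 11 of 18 and higher in 1 (12 and 1 adjusted over the list alone), with the carbonic anhydrase gene Car2 at -3.17 and Hbb-bh1 at -2.30 ± 0.17 (adjusted p = 6.40e-08, and 0.0488 with an estimated correlation). Of the endothelial lists, venous and lymphatic genes were lower in 4 of 12 and higher in 0, the same adjusted over the list alone, with Stab2 at -5.79 and Lyve1 at -4.91 (adjusted p = 0.00793, and adjusted p = 0.154 with an estimated correlation). Pan-endothelial genes were lower in 6 of 24 and higher in 2 (9 and 3 adjusted over the list alone), with Clec14a at -2.89 and Emcn, a sialomucin of veins and capillaries, at 1.32. Their adjusted p of 0.00503 was lost with an estimated correlation (adjusted p = 0.305).

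Glycolysis and hypoxia genes were higher in the caudal-half tissue in 6 of 17 and lower in 0 (13 and 0 adjusted over the list alone). Hk2, hexokinase, was at 8.44 ± 0.12 in the caudal-half tissue and 6.28 ± 0.06 in the yolk sac (n = 2 each), a difference of 2.16 ± 0.20, and Pdk1 differed by 1.62. The list's adjusted p was 7.19e-08 (0.0488 with an estimated correlation). Hox genes were higher in 5 of 13 members of groups 1 to 5 and lower in 1 (7 and 1 adjusted over the list alone), and in 8 of 19 members of groups 6 to 13 with 1 lower (11 and 1 adjusted over the list alone). Hoxd1 was at 3.33, Hoxc10 at 3.07 and Hoxd9 at 2.79. Their adjusted p of 0.00396 and 6.82e-06 were lost with an estimated correlation (adjusted p = 0.138 and 0.0900), the first also without dim genes (0.718). Somite and paraxial mesoderm genes were higher in 3 of 12 and lower in 0, the same adjusted over the list alone. They were Foxc2 (5.89 ± 0.27), Tcf15 (1.77) and Meox1 (1.40), at an adjusted p of 0.00909 (adjusted p = 0.154 with an estimated correlation). Foxc2 was also higher in the heart tube than in the yolk sac (6.88), so its difference is not particular to the caudal-half tissue. Mesenchymal genes were lower in 6 of 16 and higher in 3 (7 and 3 adjusted over the list alone), with Lum at -3.94 and the collagen genes Col1a1 and Col1a2 at -3.91 and -3.52 (adjusted p = 0.0119, and adjusted p = 0.154 with an estimated correlation). Epithelial genes were lower in 4 of 14 and higher in 0 (4 and 1 adjusted over the list alone), such as Krt8 (-2.10). The call at an adjusted p of 0.0293 was lost with an estimated correlation (adjusted p = 0.183), without the second caudal array (0.0617) and without the first yolk sac array (0.053).

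Over all genes limma called 767 higher and 885 lower in the caudal-half tissue than in the yolk sac (4.22% and 4.86%). The largest upward difference after Foxc2 was Pmepa1 (4.62), a membrane protein induced by TGF-beta, followed by the cation channel gene Trpc6 (4.59). In 277 called genes, among them Apob, Foxc2, Hoxd1, Pmepa1, Trpc6, Gfi1, Sox2 and Zic2, the lower mean was within the range of the bacterial controls. Without a single caudal array the counts fell to 222 or 262 higher and 416 or 480 lower, without a yolk sac array to 290 or 447 higher and 476 or 588 lower, and without either heart tube array to 475 higher. Of the genes named here, Tcf15 lost its call without either caudal array or the first yolk sac array, Meox1 without the second caudal array or either yolk sac array, and Gfi1 without either caudal array or the first yolk sac array (highest limma adjusted p 0.148).

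Transcription factors of blood and haemogenic endothelium bear on the question of which of these endothelia carry a blood-forming programme. As a list of 22 genes they passed camera in none of the 3 comparisons, with camera adjusted p of 0.957 for heart tube against caudal-half tissue, 0.246 for heart tube against yolk sac and 0.0953 for caudal-half tissue against yolk sac. Limma's fry did pass them, upward, in both comparisons with the yolk sac (fry adjusted p = 0.0206 for the heart tube and 0.0250 for the caudal-half tissue). Single members differed. Gfi1, a repressor that silences endothelial genes as blood emerges, was at 5.52 ± 0.24 in the caudal-half tissue and 3.03 ± 0.42 in the yolk sac (n = 2 each), a difference of 2.49 ± 0.43 with a limma adjusted p of 0.0188. Myb, a factor of definitive haematopoiesis, differed by -1.51 between heart tube and caudal-half tissue and by 1.43 between caudal-half tissue and yolk sac. Lmo2 differed by -1.89 between heart tube and caudal-half tissue and by 1.48 between caudal-half tissue and yolk sac. Etv2, an early endothelial and blood factor, was higher than in the yolk sac by 3.40 in the heart tube and 2.92 in the caudal-half tissue. Cbfa2t3, a corepressor, was higher in the heart tube than in the caudal-half tissue (1.73) and yolk sac (1.03). Gata1 read 2.84 to 3.29 in the 3 tissues, within the range of the bacterial controls, and passed no test. In the heart tube against caudal-half tissue comparison 3 of the 22 genes were higher and 3 lower (4 and 5 adjusted over the list alone). Against the yolk sac 4 were higher and 0 lower in the heart tube (5 and 1), and 6 higher and 0 lower in the caudal-half tissue (6 and 2).

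Several of these single-gene calls rested on all arrays being present. Gfi1 in caudal-half tissue against yolk sac lost its call without either caudal array or the first yolk sac array (limma adjusted p up to 0.104), Myb without the first caudal or second yolk sac array (up to 0.103), Lmo2 without either caudal or the second yolk sac array (up to 0.0773) and Etv2 without either caudal array (up to 0.096). Against the caudal-half tissue, Myb lost its call in the heart tube without either heart tube array or the first caudal array (up to 0.132), and Lmo2 without the first heart tube array or either caudal array (up to 0.0534). Cbfa2t3 against the yolk sac was lost without either heart tube array or the second yolk sac array (up to 0.0899).

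For Runx1, the transcription factor required for blood to emerge from endothelium, the 6 probe sets disagreed on the size of the differences. All 6 read lower in the heart tube than in the other tissues, though not all passed. Between caudal-half tissue and yolk sac they also differed in sign. The brightest, which represents the gene by the fixed rule, read 6.27 ± 0.01 in the heart tube, 6.48 ± 0.21 in the caudal-half tissue and 6.55 ± 0.16 in the yolk sac (n = 2 each) and passed no test. The other probe sets were examined after those values were seen. The probe set with the largest difference was lower in the heart tube than in the caudal-half tissue by -3.70 ± 0.24 (limma adjusted p = 0.00115 over all named probe sets) and than in the yolk sac by -1.47 ± 0.24 (0.0150). It was higher in the caudal-half tissue than in the yolk sac by 2.24 ± 0.24 (0.00524). Another gave -2.93 ± 0.35 for heart tube against caudal-half tissue and 1.75 ± 0.35 for caudal-half tissue against yolk sac. In all, 3 of the 6 probe sets were lower in the heart tube than in the caudal-half tissue and 2 were higher in the caudal-half tissue than in the yolk sac. With the mean of all 6 probe sets the gene was higher in the caudal-half tissue than in the yolk sac by 0.76 (limma adjusted p = 0.0317). On the probe set with the largest difference the heart tube arrays (2.36 and 2.52) and the mean of the yolk sac arrays (4.19 and 3.63) were within the range of the bacterial controls, as was the mean of the heart tube arrays (3.24 and 4.04) on the one at -2.93, so these sizes rest on signals near background.

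**Figure D3:**
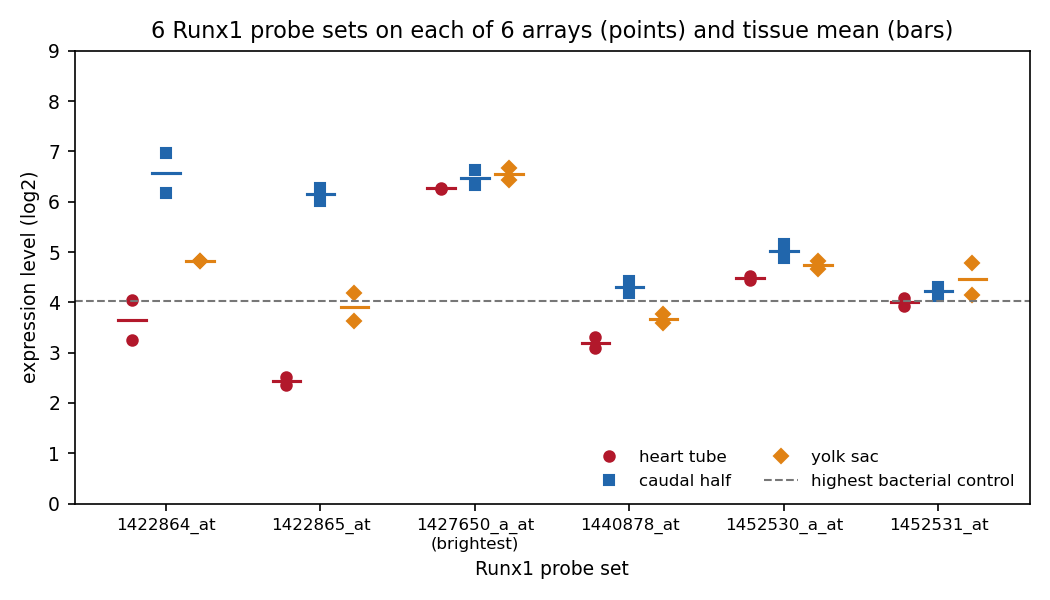
Expression level (log2) of the 6 Runx1 probe sets, with points for the 2 arrays of each tissue, short bars for means and a dashed line at the highest bacterial control. The brightest probe set is level across tissues at 6.27 to 6.55, while the probe set with the largest difference gives -3.70 between heart tube and caudal-half tissue.

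Flow-responsive genes and genes of the dissociation stress response were also among the lists fixed beforehand. The 8 flow-responsive genes had 2 higher and 0 lower in the heart tube than in the caudal-half tissue (Klf4 1.08 and the nitric oxide synthase gene Nos3 0.91, the same adjusted over the list alone). Both lost their calls whichever of the 4 heart tube and caudal arrays was left out (limma adjusted p up to 0.184). The list passed there (camera adjusted p = 0.00828, and adjusted p = 0.216 with an estimated correlation) but not for heart tube against yolk sac (0.0683) or caudal-half tissue against yolk sac (0.945). The 15 genes of the dissociation stress response had 0 higher and 2 lower in the heart tube than in the caudal-half tissue (0 and 3 adjusted over the list alone), Ier3 (-2.39) and Fos (-1.16). The call at an adjusted p of 0.00792 was lost with an estimated correlation (adjusted p = 0.216), and the list missed the threshold in the other comparisons (0.370 and 0.605). Single members moved both ways there. Against the yolk sac, 2 were higher and 7 lower in the heart tube (5 and 7 adjusted over the list alone). In the caudal-half tissue 4 were higher and 1 lower than in the yolk sac (6 and 4). Fos lost its call against the caudal-half tissue without either heart tube array or the first caudal array.

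Leukocyte, platelet, neural and cell cycle genes as lists passed in no comparison in limma's camera. Limma's fry passed some of these tests, such as neural and cell cycle genes for heart tube against caudal-half tissue (fry adjusted p = 0.00476 and 0.00595). The 20 macrophage and leukocyte genes, of which 11 or 12 per tissue were within the range of the bacterial controls, gave camera adjusted p of 0.338, 0.529 and 0.726. The 12 platelet genes gave 0.349, 0.887 and 0.429, the 16 neural genes 0.0744, 0.887 and 0.0827, and the 19 cell cycle genes 0.0827, 0.949 and 0.144, in the order heart tube against caudal-half tissue, heart tube against yolk sac and caudal-half tissue against yolk sac. The median and the mean of a list differed in sign in several tests. For heart tube against caudal-half tissue these were mesenchymal (median -0.17, mean 0.81) and platelet genes (-0.04 and 0.10). For heart tube against yolk sac they were blood transcription factors (-0.05 and 0.33), neural (-0.10 and 0.19), somite (-0.17 and 0.56), mesenchymal (0.11 and -0.13) and cell cycle genes (0.02 and -0.03). For caudal-half tissue against yolk sac they were cushion (0.14 and -0.04), flow-responsive (0.04 and -0.09), macrophage (0.05 and -0.12) and dissociation stress genes (-0.01 and 0.19), with platelet genes at 0.00 and -0.17. Single members passed: Sox2 and Zic2 were higher in the caudal-half tissue than in the yolk sac by 3.61 and 3.62, and the neuronal tubulin gene Tubb3 was higher in the heart tube than in the caudal-half tissue by 4.29. Of the 16 neural genes, 2 were higher and 4 lower in the heart tube than in the caudal-half tissue. In the caudal-half tissue 4 were higher and 1 lower than in the yolk sac. The remaining tests of lists named above also missed the threshold. They were endocardial (0.364), cushion (0.887), arterial (0.215) and cardiomyocyte genes (0.726) for caudal-half tissue against yolk sac, visceral endoderm (0.364), erythroid (0.945) and somite genes (0.0683) for heart tube against caudal-half tissue, and somite (0.630), mesenchymal (0.789) and glycolysis genes (0.370) for heart tube against yolk sac. Of the 4 measured sex-linked genes only Eif2s3y passed, in caudal-half tissue against yolk sac (0.79), and that call was lost whichever of the 6 arrays was left out (limma adjusted p up to 0.168).

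**Figure D4:**
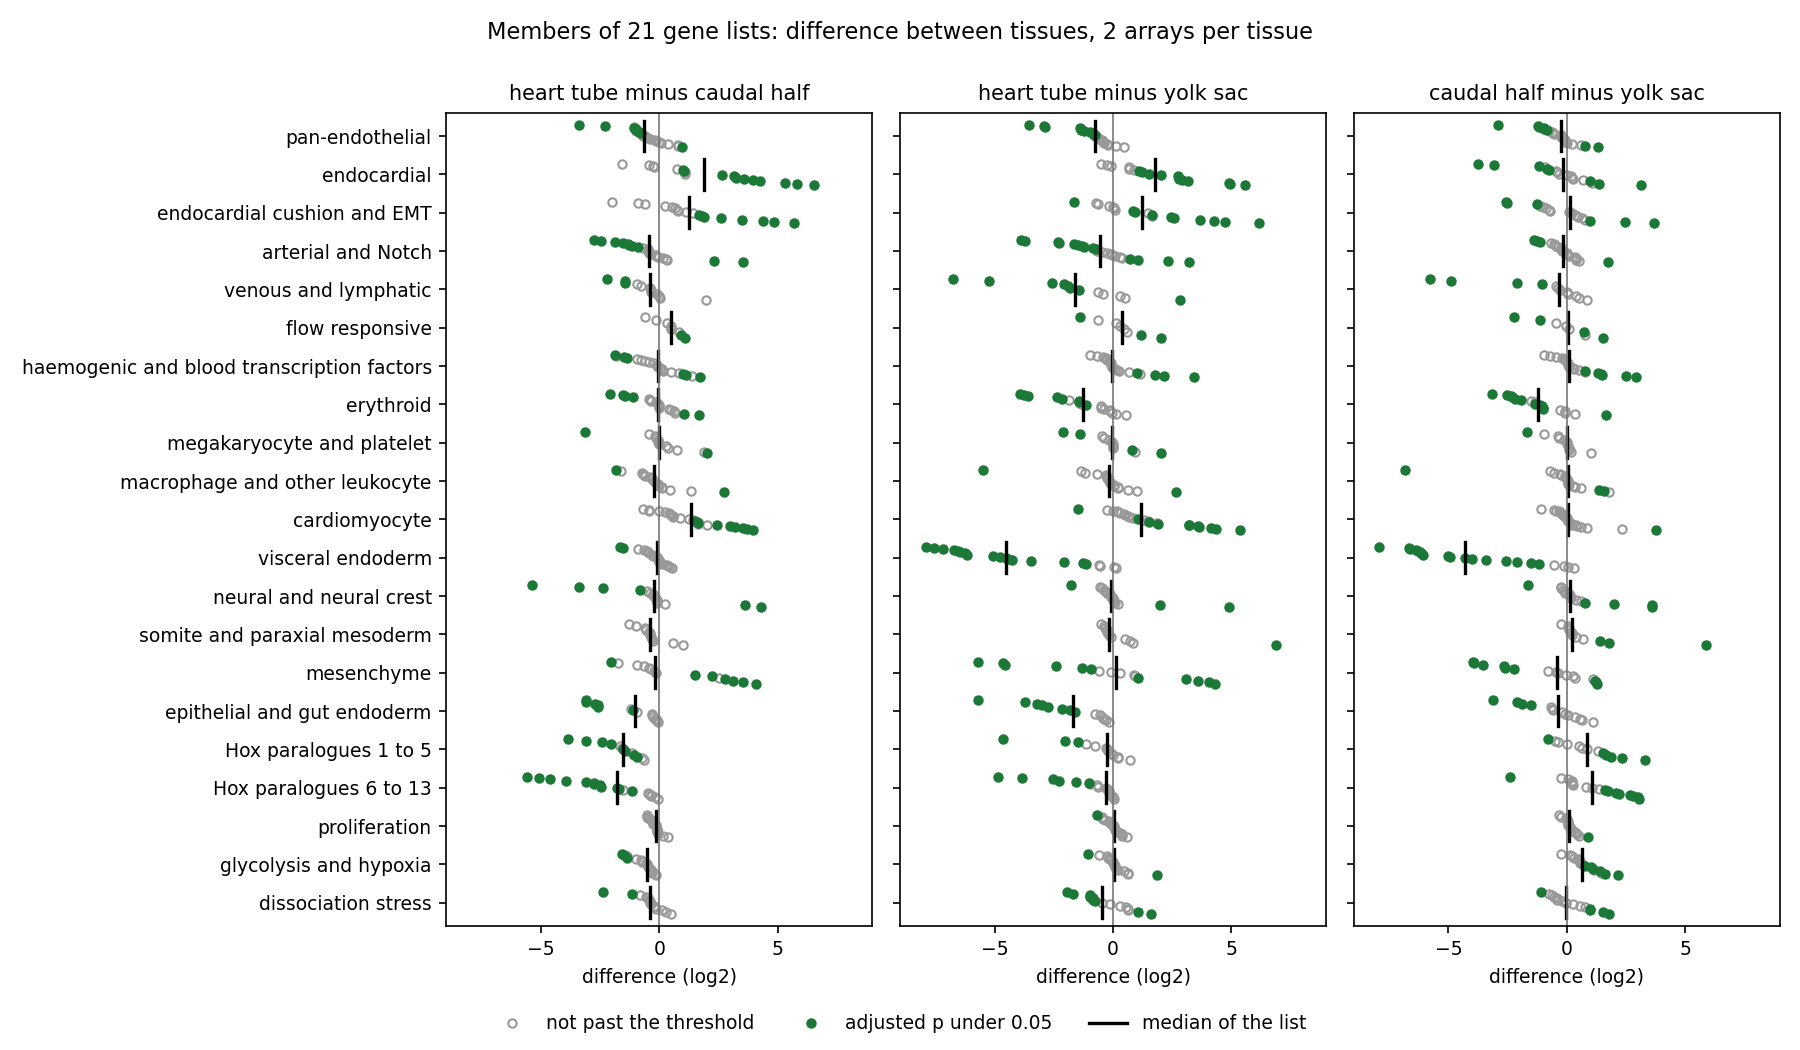
Difference (log2) of every measured member of 21 gene lists in the 3 comparisons, with filled points for genes at a limma adjusted p under 0.05, open points for the others and a black bar at the median of the list. The median of the endocardial list is 1.87 for heart tube minus caudal-half tissue and -0.16 for caudal-half tissue minus yolk sac, and that of the visceral endoderm list is -4.53 and -4.31 in the comparisons with the yolk sac.

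Across all 3 tissues 2465 of 18193 genes differed in the limma F test (13.5%). Genes apart from both other tissues in one direction were most numerous in the yolk sac, with 579 higher and 324 lower. The heart tube had 306 higher and 271 lower, and the caudal-half tissue 169 higher and 148 lower. Because both comparisons of a tissue use its 2 arrays, overlap arises without any difference: simulated groups with no difference shared on average 304 and 238 genes for the yolk sac, 185 and 199 for the heart tube, and 157 and 179 for the caudal-half tissue. The highest of 100 simulations was 339 and 268, 212 and 225, and 175 and 202 in the same order, so only the caudal counts did not exceed it. These simulations filled lists of the observed sizes with the top genes, without a threshold. They therefore cannot show that the caudal genes are false calls. With the threshold, a simulated comparison without any change called 0 of 18193 genes. Independent lists would share 59.1 and 39.5, 26.8 and 32.2, and 20.3 and 25.3. The arrays of a tissue were not divided between comparisons, since each part would hold 1 array, and part of any excess may come from sharing them. Apart in the heart tube were Pdlim3, Bmper, Has2, Ccdc141 and Gata5 upward and Esm1, a gene of endothelial tip cells, Pdpn, Depp1, Hoxb5 and Hoxd8 downward. The caudal-half tissue stood apart with Sox2, Zic2, Hoxd1, Hoxc10 and Hoxa9 upward and Dpp4, Tbx20, the matrix gene Tnc, Bace2 and the caveolar gene Cavin2 downward. The yolk sac stood apart with Ttr, Apob, Rbp4, Afp and Spink1 upward and Foxc2, Pmepa1, Trpc6, Tnnt2 and Nr2f1 downward. For Esm1, Pdpn, Depp1, Dpp4, Bace2 and Nr2f1 the lower means were within the range of the bacterial controls.

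These counts fell whichever array was left out. Each such fit has fewer arrays and leaves a tissue with a lone array, so part of the fall comes by construction. Without the first or second heart tube array the F test called 1315 and 1397 genes, without the first caudal array 1592 and without the first yolk sac array 1570. The higher and lower counts of the heart tube fell to 137 and 106 without its first array, 149 and 126 without its second, 150 and 106 without the first caudal array and 194 and 146 without the second. The yolk sac had 337 and 119, 360 and 109, 327 and 109, and 338 and 109 genes in the same order, not all of them among the original calls, and 328 and 155 without its first array. The caudal-half tissue had 67 and 56, 76 and 56, 60 and 55, and 95 and 74 genes in that order (of the 95 and 74, 52 and 61 were among the original 169 and 148), 90 and 92 without the first yolk sac array and 97 higher without the second. Hoxa9 lost its call against the heart tube without the first caudal array (limma adjusted p = 0.0521), and against the yolk sac without either caudal array or the second yolk sac array (up to 0.0770). Bace2 lost its call against the heart tube without either heart tube array or the first caudal array (up to 0.0745), and against the yolk sac without the first caudal array (0.0552).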

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

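Probe sets without a gene of their own are outside every comparison above, and some of them carried a signal that differed among tissues. In limma's F test over all probe sets, 537 of 10092 such probe sets differed (5.32%), against 3383 of 34945 probe sets with a gene (9.68%). No control samples exist against which to set this signal. Groups of 2 arrays are too small to look for arrays that stand apart from their group.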

How the results depend on the processing

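The minimum difference on the literal scale and the removal of genes within the control range were chosen after seeing the data. Leaving out an array leaves its tissue with a lone array, assumed to vary like the other groups. Of 275 named gene and comparison pairs 247 were called. Without each array in turn, 52 of 79 calls held for heart tube against caudal-half tissue, 67 of 85 for heart tube against yolk sac and 49 of 83 for caudal-half tissue against yolk sac, with 0 changes of sign. Signal over background limits 67 called pairs whose lower mean is within the control range. Counts without each array ranged, higher then lower, over 208 to 493 and 168 to 406 for heart tube against caudal-half tissue, 387 to 764 and 549 to 1030 for heart tube against yolk sac, and 222 to 475 and 416 to 680 for caudal-half tissue against yolk sac. They ranged over 1315 to 1792 for the F test, 137 to 262 and 106 to 190 for genes apart in the heart tube, 60 to 97 and 55 to 104 in the caudal-half tissue, and 327 to 405 and 109 to 229 in the yolk sac, with fewer arrays by construction. A minimum difference of 0.5, which by construction calls fewer genes, gave 232 and 174, 366 and 532, and 187 and 385 in the 3 comparisons and 144 and 93, 48 and 49, and 256 and 76 for genes apart. On the literal log2 scale it gave 299 and 242, 493 and 697, 294 and 505, 190 and 138, 69 and 67, and 337 and 123. A trended variance gave 1229 genes higher in caudal-half tissue than yolk sac (754 of them among the 767), 258 apart upward in the caudal-half tissue (164 shared) and 594 apart downward in the yolk sac (318 shared). Without dim genes the last count was 492 (275 shared). With only the 4 arrays of the 2 tissues, 475 genes were higher in caudal-half tissue than yolk sac. For the trend and the dim genes the cause was not tested. All probe sets, of which there are more than genes, gave 868 higher in heart tube than caudal-half tissue, 1742 higher in heart tube than yolk sac, 3920 in the F test and 553 apart upward in the heart tube. The F test with a minimum difference and the counts of genes apart with 4 arrays were not run. Robust variances, the mean of probe sets, removal of shared sequences, control-range removal, cyclic loess and centring moved no count by over 1.5 times. Centring moved the median difference of all genes for heart tube against caudal-half tissue from -0.08 to -0.11.

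Differences that changed sign were all uncalled: Myb for heart tube against yolk sac became 0.23 with the mean of probe sets, 0.44 without shared sequences and -0.33 to 0.17 without each array. For caudal-half tissue against yolk sac, Pecam1 became 0.00577 with centring and -0.14 to 0.13 without each array, Ptprc -0.000953 with the mean of probe sets, Runx1 0.76 with the mean of probe sets (limma adjusted p = 0.0317) and -0.22 to 0.0752 without each array, and Nfatc1 -0.0674 with cyclic loess and -0.56 to 0.58 without each array. The cause was not tested. Of 33 list calls 12 held with an estimated correlation. Dim genes left out ended the call for mesenchymal genes in heart tube against caudal-half tissue (limma camera adjusted p = 0.206) and Hox 1 to 5 in caudal-half tissue against yolk sac (0.718), and the mean of probe sets that for venous genes in heart tube against caudal-half tissue (0.0614). The replicate number was not taken to pair arrays, since deviations of same-numbered arrays over all genes correlated at 0.0468, -0.00681 and 0.0189. The hybridisation controls, however, were higher in the first replicate of every tissue, by 0.250 to 0.376, so a shift shared by replicate number is not excluded. With the replicate block the counts were 400 and 376, 814 and 1062, 590 and 766, 2070 in the F test, and 256 and 218, 128 and 109, and 511 and 254 apart. Of the named calls 16 were lost and 1 was gained, and 2 list calls were lost (mesenchymal genes in heart tube against caudal-half tissue, 0.0544, and epithelial genes in caudal-half tissue against yolk sac, 0.103).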

Other observations

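Nanog and Pou5f1, genes of pluripotency and the germ line, had their highest levels in the caudal-half tissue. Nanog was at 6.83 ± 0.11 (SD, n = 2) in the caudal-half tissue, 2.46 ± 0.24 in the heart tube and 3.98 ± 0.13 in the yolk sac, and Pou5f1 at 7.85 ± 0.32, 3.73 ± 0.03 and 4.89 ± 0.16. Both were chosen after their values were seen. Of the endothelial genes named whatever their test, Cdh5, which encodes VE-cadherin, was at 10.63 ± 0.01 in the caudal-half tissue and 10.87 ± 0.02 in the yolk sac, and the heart tube differed from these by -0.63 and -0.87. Kdr, a receptor of VEGF, was at 9.94 ± 0.33 in the heart tube, 11.03 ± 0.31 in the caudal-half tissue and 11.27 ± 0.25 in the yolk sac. Heart tube and yolk sac differed in both genes at limma adjusted p under the threshold, and both calls were lost without single arrays (up to 0.101 for Cdh5 and 0.114 for Kdr). The mean of the 9 hybridisation controls was higher in the first replicate than in the second of every tissue, by 0.250 in the heart tube, 0.366 in the caudal-half tissue and 0.376 in the yolk sac.

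In the 3 patterns that follow, the tests of a lower share of endothelial cells and of single replicates were chosen after their results were seen. The gene lists of germ cells, tail bud, heart muscle and visceral endoderm were written after the main results but before the values of their genes were looked at. For each of these lists the bound fixed beforehand against its explanation was that no more than 1 gene would be higher than in both other tissues. The tail bud and heart muscle lists met that bound, and by it alone both explanations would have been set aside. The verdict was changed to undecided after these values were seen. Both lists had exactly 1 such gene, at the bound and not below it by more than counting error. The bound also counted genes within the range of the bacterial controls in every tissue (10 of 28 heart muscle and 5 of 16 tail bud genes), which decide nothing. It counted genes already above that range in both other tissues too (16 and 5). That is a weak reason, since such genes did pass. The germ cell list held 8 of them and the visceral endoderm list 11, and some in each list passed. Sall4 passed at 10.52 in the caudal-half tissue, against 8.98 in the heart tube and 9.40 in the yolk sac. Des and Cyp26a1, the genes that passed in the heart muscle and tail bud lists, were above that range in both other tissues as well. The effect of a small share of added cells on such genes was not tested. Both list medians lay above nearly all random lists, which was 1 part of each prediction. The other part, at least 3 genes higher than in both other tissues, failed for both lists. The reasons for the change were also found after the values were seen. The verdict on a lower share of endothelial cells was likewise changed, from argued against to undecided.

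Some germ cell genes, among them Dppa3, were higher in the caudal-half fraction. As a hypothesis, primordial germ cells, which can carry CD31 and so pass the gate, could be part of that fraction. Of 20 further germ cell genes, 7 were higher in the caudal-half tissue than in both other tissues (Prdm1, Sall4, Lin28a, Alpl, Zfp42, Esrrb and Rhox6), with a median difference of 1.05, above all random lists matched on expression (-0.09 to 0.19 for the central range), and Rhox6 was at 8.28 against 5.27 and 6.93. The rest did not pass against both, among them the abundant Ifitm3 (11.09, against 9.36 in the heart tube and 11.15 in the yolk sac). In every tissue 7 of the 20 were within the range of the bacterial controls. Sall4 (8.98 and 9.40) and Lin28a (8.22 and 9.66) were also well above that range in the heart tube and yolk sac. Of 16 genes of tail bud progenitors, 1 was higher (Cyp26a1), with a median of 0.28 above 99.62% of random lists, but Wnt5a (7.91 against 6.27), Greb1 (7.87 against 6.25), Hes7 (4.93 against 3.55) and Sp5 (4.65 against 3.94) were at higher levels in the heart tube than in the caudal-half tissue, so tail bud cells, which selection for CD31 would remove, are left open on mixed values. Expression of these genes by caudal endothelium itself was not tested and stays open too.

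Of 24 heart muscle genes 8 were higher in the heart tube fraction than in the caudal-half fraction, and 10 were higher and 1 lower than in the yolk sac fraction. A lower share of endothelial cells would lower all pan-endothelial genes alike. Their differences from the other tissues ran from -3.47 to 0.54, with an SD 5.34 times the median standard error. Endothelia of different tissues would differ unevenly in any case, and the list was lower as a set in camera. Adjusted over the list alone, 17 of 24 genes were lower and 0 higher than in the yolk sac. Against the caudal-half tissue 14 were lower and 3 higher. Both camera calls were lost with an estimated correlation (adjusted p = 0.148 for the yolk sac and 0.217 for the caudal-half tissue). A lower share of endothelial cells stays open. Cardiomyocytes or their RNA in the gate, which the selection for CD31 would remove, were tested with 28 further genes. Of these, 1 was higher than in both other tissues (Des), with a median of 0.28 above all random lists, while the abundant Tpm1 (12.01, against 12.33 and 12.10) and Atp2a2 (10.84, against 10.79 and 10.74) did not stand out, Popdc2 (1.65), Ldb3 (1.15), Fhl2 (1.12) and Rbm24 (1.11) were above the mean of the other tissues without passing, and 10 of the genes were within the range of the bacterial controls everywhere. This leaves cardiomyocytes and expression by the endocardium itself both open, the latter untested.

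Of 21 visceral endoderm genes 17 were higher in the yolk sac fraction in each of its comparisons. A single deviant array is argued against, since the median difference of the list was 4.75 with the first yolk sac array and 4.33 with the second. The limma calls already required both yolk sac arrays to be alike, so these medians add little to them. Of 21 further genes, 11 were higher in the yolk sac than in both other tissues, with a median of 1.72 above all random lists, among them Rhox5 (9.67 against 7.52 and 8.07), Lgals2 (7.99) and Folr1 (7.17). This is consistent with visceral endoderm cells or their RNA in the sorted fraction, a hypothesis, since selection for CD31 would remove cells without it. Expression by yolk sac endothelium was not tested and stays open.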
